A study of Gossypium hirsutum with 18 samples.

How the data were processed

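RNA from ovules of upland cotton (Gossypium hirsutum) was sequenced in 18 libraries, per the labels. The libraries fell into 6 groups of 3 replicates, made by 2 genotypes, Xu142 and Xu142fl, at 3 days counted from flower opening: -1, 0 and 1 day post-anthesis (DPA). As background, Xu142 is a fiber-bearing line and Xu142fl is a fuzzless and lintless mutant derived from it. The labels give total RNA as the molecule and a standard Illumina library preparation, and they say nothing about separate plants. P-values of single genes therefore measure only the spread between these samples, which may be technical. Fisher's exact tests used below count genes measured in the same libraries, which are not independent, and hold no spread between libraries. Groups and replicate numbers were taken from the sample titles.

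The authors deposited 3 tables, 1 per day, each with the 6 libraries of that day. The aligner, the counting and testing tools, the use of strand, the annotation and the genome build are not given in the sources used here. Each table lists only genes that the authors had called. In every listed gene the deposited adjusted p-value was under 0.05, and the deposited log2 fold change was at least 1 in size. The library columns hold a deposited signal, normalised reads per gene. Within each library all listed values were whole multiples of 1 value, so that 100% of them gave whole reads within a tolerance of 0.001. They are thus read counts divided by 1 factor per library, between 0.733 and 1.76. The deposited log2 fold change was Xu142 over Xu142fl, per the file headers, and its sign was turned here, so that a positive value means higher in Xu142fl. It was smaller than the plain log2 ratio of the deposited group means, with a median ratio of 0.680 at -1 DPA, 0.657 at 0 DPA and 0.969 at 1 DPA. Because the shrinkage differed between days, the log2 ratios given here are those of the group means. Gene start, end and length in bases are as deposited by the authors, on their own build, per the file headers. Per the file headers, the tables also pair each gene with a description, and protein names were taken from its best Swiss-Prot match. Such a name was present for 53.2%, 55.1% and 70.1% of the listed genes at -1, 0 and 1 DPA. Names of this kind mark the closest described protein and not a tested function.

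Because the tables hold called genes only, 3 limits follow. Library depth is unknown beyond the listed genes, whose recovered reads are given with the results. A gene absent from a table was either unchanged or below the authors' criteria there, and these cannot be told apart from the table alone. Apart from the interaction fits, no count adjusted over the list alone was made, and no share of called genes could be set against an unselected background. Each table was normalised on its own, so that tests were made within a table, except the interaction fits named later.

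The plan made before the data were examined named an edgeR test of raw counts for all genes, and for tables of called genes the authors' own calls as the result. The second case applied. The number of genes the authors tested was recovered from the ratio of adjusted to raw p-values, 58161 at -1 DPA, 57326 at 0 DPA and 61474 at 1 DPA. As alternatives, the recovered reads of the listed genes were refitted with edgeR 4.0.16 (quasi-likelihood), limma 3.58.1 on log2(value + 1) and log2(value + 0.1), and DESeq2 1.42.0, in R 4.3.3, with Benjamini-Hochberg adjustment over the number of genes the authors tested. The edgeR refits used the authors' factors. Further alternatives left out each library in turn, used a replicate block, required a mean of 10 or an adjusted p under 0.01, and took TMM factors or DESeq2 size factors from the listed genes. Factors from a list of called genes center the list on itself, and they moved the median log2 fold change, TMM by -0.17, 1.10 and 1.20 and DESeq2 by -1.11, 1.56 and 1.24 at -1, 0 and 1 DPA. Directions under such factors are therefore no test of the authors' directions. On simulated counts with 200 changed genes among the listed ones, the edgeR refit called 62%, 1% and 32% of the 2-fold changes and 98%, 54% and 89% of the 4-fold changes at -1, 0 and 1 DPA, and 0 unchanged genes. With 200 changed genes and adjustment over all genes tested, the cut was stricter than in the refits. The rates are therefore not the sensitivity of the refits, and few unchanged genes could have been called.

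The 43 gene lists were fixed before the data were examined, as search terms applied to the description of each gene. They cover regulators of epidermal and fiber cells, histone H3K27 methylation, cell walls, lipids, hormones, stress and housekeeping groups. Lists of photosynthesis, pollen and seed storage genes were meant to stand for green tissue, pollen, and embryo or endosperm. For each list and day the split into higher and lower members was set against that of the other listed genes with Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the lists of that day. Such a test compares directions among called genes and says nothing about how many genes of a list changed. Alternatives matched the search terms to the protein name alone, kept members with a mean of at least 100 normalised reads, or kept 1 gene per protein name and direction. Another planned one, a deposited log2 fold of at least 1, kept every listed gene and so repeats the main result. Simulated directions at 1 DPA, with 1 list forced, called that list and 0 others. A further 2 lists were chosen after the data were seen.

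Named genes followed a rule fixed beforehand. It asked for a deposited call and a mean of at least 100 normalised reads in the higher genotype. Among such genes it took the 2 members with the lowest adjusted p of each list with at least 3 listed members. It also took the 6 highest and the 6 lowest genes by deposited log2 fold change. These further needed no overlap between the 3 values of each genotype, and a description naming a product. Called members of the homeodomain (HD-Zip IV) and H3K27me3 lists, and called MYB factors of the MIXTA and WER kind, were taken whatever their level. The rule picked 60, 77 and 117 genes at -1, 0 and 1 DPA, of which the text names a part. Genes outside it are said to be chosen after their values were seen, and counts over the genes of 1 protein name within a list were chosen in the same way.

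Errors are the SD over 3 libraries, or the SE of the log2 ratio. A ratio against a genotype with no read in any of its 3 libraries was computed against 3 reads over the group and is given as a lower bound. With 1 to 6 reads, the ratio printed with a 95% counting interval divides by those reads over the summed factors of the 3 libraries. Such intervals and bounds cover counting error only. Upland cotton is an allotetraploid with paired A and D copies of most genes, and reads from near-identical copies may have been split between them, so that the values of single copies are uncertain to that extent.

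Replicate numbers are shared between genotypes. Whether they pair the libraries was checked by correlating, across genes, the deviations of same-numbered libraries from their group means. At 0 DPA all 3 pairs were above 0.1 (0.168, 0.101 and 0.201 over 1301 genes, which are not independent replicates), so that the numbers were taken to pair the libraries there, from the values alone. Pairs of unlike number ran from -0.155 to 0.021 at 0 DPA. At 1 DPA, Xu142 replicate 2 and Xu142fl replicate 3 reached 0.149, so that a value of this size alone does not show pairing. Libraries of 1 group correlated at 0.935 to 0.989 across the listed genes on the log2 scale, and no library was a copy of another.

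Chromosome and subgenome counts used the positions in the tables. Interaction fits with edgeR compared the genotype difference between days among genes listed at both. Marker levels, thinning of reads and regroupings of the libraries are described beside their results. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps. The table of reference gene names given for the species uses other identifiers, matched no gene of the tables and was not used here. The authors' columns of group means were not used, since they equal the means of the library columns.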

Results

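Gene expression in ovules of Xu142 and of the fuzzless-lintless mutant Xu142fl was compared at -1, 0 and 1 DPA, the days around flower opening when fiber cells start to protrude from the ovule epidermis. The title of the series concerns the histone mark H3K27me3 in fiber initiation, and the comparison at each day asks which transcripts differ between the genotypes. Each genotype and day had 3 libraries. Recovered reads over the listed genes ran from 210953 to 257804 per library at -1 DPA, from 130502 to 346187 at 0 DPA and from 2833696 to 6388114 at 1 DPA. These sums cover listed genes only and are not library depths. Values below are normalised reads, Xu142 first, as mean ± SD (n = 3), and log2 ratios are Xu142fl over Xu142 ± SE. Higher and lower always refer to Xu142fl. Listed genes are those the authors had called.

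At -1 DPA, transcripts of the morning clock factor LHY were lower in Xu142fl. The A-subgenome copy Gh_A12G134600 (chromosome A12, 79806591 to 79813351) stood at 646 ± 219.6 against 40.8 ± 0.871, a log2 ratio of -3.99 ± 0.28. The D-subgenome copy Gh_D12G134800 stood at 499.9 ± 130.5 against 60.1 ± 6.54, a log2 ratio of -3.06 ± 0.24. PROTODERMAL FACTOR 2 (PDF2), a homeodomain factor of epidermal identity, was lower in both listed copies, with 2466 ± 108 against 460.4 ± 282 for Gh_A06G172400 (chromosome A06, 113669688 to 113673221) and 2471 ± 32.6 against 526 ± 285 for Gh_D10G015500. The log2 ratio of Gh_A06G172400, -2.42 ± 0.51, was -3.04 without Xu142fl replicate 3. A beta-tubulin transcript, Gh_A07G127700, which encodes a subunit of microtubules, fell from 8372 ± 527 to 1586 ± 337.

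Further transcripts were lower at -1 DPA. The plasma membrane aquaporin PIP-type 7a (Gh_D06G194600) stood at 1748 ± 118 against 182 ± 82.2 and PIP2-2 (Gh_D05G101500) at 134 ± 75.02 against 10.8 ± 1.17. Of the 11 listed genes of very-long-chain fatty acid elongation, whose products feed waxes and membranes, 1 was higher and 10 were lower, which did not pass the test (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0650; 0.0650 to 0.549 over its alternatives). Among the lower ones, long chain acyl-CoA synthetase 1 (Gh_A07G138800) had a log2 ratio of -1.17 ± 0.12. A lipid-transfer protein (Gh_D10G123600) fell from 4973 ± 467 to 2124 ± 133. ACCELERATED CELL DEATH 6 (Gh_D04G211300), a regulator of defense and cell death, fell from 497 ± 76.5 to 25.3 ± 12.7. The acid invertase Gh_D09G206200, which splits sucrose, had a log2 ratio of -1.90 ± 0.28.

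Heat-shock genes formed the single fixed list that passed at -1 DPA, with 1 member higher and 12 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0333; 0.00451 to 0.158 over its alternatives). With 1 gene kept per protein name and direction the call ended, at the upper bound of that range. Heat shock factor HSF30 (Gh_D13G216300), which switches on chaperone genes, stood at 375 ± 26.9 against 93.4 ± 4.50. The chaperone heat shock cognate protein 80 (Gh_D13G150100) stood at 1455 ± 256 against 542 ± 17.3. The marker lists did not pass at -1 DPA. Photosynthesis genes were 3 higher and 10 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.232; 0.0131 to 0.843 over its alternatives), the pollen and anther list 4 higher and 3 lower, and the seed storage list 0 higher and 3 lower. Of the 7 pollen members 1 matched by protein name, and of the 3 seed storage members 0. In these lists 5 and 3 members also sat in another list, so that both say little about pollen, embryo or endosperm.

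Other transcripts were higher in Xu142fl at -1 DPA. 1-aminocyclopropane-1-carboxylate synthase (Gh_A12G256700), the enzyme that makes the ethylene precursor, rose from 138 ± 9.56 to 935 ± 159.9. The wax alkane enzyme ECERIFERUM 1 (Gh_A06G185800) rose from 31.1 ± 5.57 to 262 ± 15.1, and the wall-loosening enzyme xyloglucan endotransglucosylase/hydrolase 2 (Gh_D02G024500) had a log2 ratio of 3.01 ± 0.28. All 9 listed peroxidases and redox enzymes were higher, which did not pass the test (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0650; 0.0650 to 0.469 over its alternatives), and among them peroxidase 5 (Gh_D12G264800) stood at 336 ± 17.0 against 1111 ± 109. Several transcripts were near the floor in Xu142. The calcium-binding protein CML50 (Gh_D03G083700, chromosome D03, 25950780 to 25953344) stood at 17.4 ± 4.33 against 893 ± 73.6, the ubiquitin ligase XBAT32 (Gh_A08G097700) at 36.5 ± 2.58 against 906 ± 128 and the transporter NRT1/PTR FAMILY 2.11 (Gh_A12G196600) at 12.4 ± 1.96 against 374 ± 26.3. A thioredoxin-like protein named TxlA (Gh_D06G014800) stood at 7.27 ± 2.59 against 244 ± 42.1 and the kinase CDPK1 (Gh_D13G003200), a sensor of calcium, at 17.5 ± 1.52 against 178 ± 3.15. The MYB factor WER (Gh_D04G061400), of a kind that sets root hair and trichome cell fate, rose from 30.5 ± 2.996 to 103 ± 16.1.

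The authors' deposited table at -1 DPA listed 872 of 58161 tested genes, of which 479 were higher and 393 lower in Xu142fl, and the highest adjusted p in it was 4.93e-05. Among the 610 annotated genes 291 were higher and 319 lower, so that the excess of higher genes lay in the unannotated transcripts (188 higher, 74 lower). The edgeR refit called all 872. DESeq2 with size factors from the listed genes, which moved the median log2 ratio by -1.11, gave 308 higher and 393 lower, or 43.9% higher against 54.9%.

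At 0 DPA the pair of HDG11 genes, homeodomain factors known from trichome branching, were far lower in Xu142fl. The D-subgenome copy Gh_D12G292500 (chromosome D12, 62292775 to 62298304) stood at 587 ± 47.7 against 30.3 ± 19.5, a log2 ratio of -4.28 ± 0.54, or -4.95 without Xu142fl replicate 1. The A-subgenome copy Gh_A12G298900 (chromosome A12, 105389156 to 105394596) stood at 402 ± 49.1 against 24.5 ± 12.8, a log2 ratio of -4.03 ± 0.45. Expansin-A8 (Gh_D10G123800, chromosome D10, 19208807 to 19210097), which loosens cell walls, fell from 1813 ± 432 to 73.8 ± 38.6. The pectate lyase 5 pair, enzymes that cut pectin, stood at 265 ± 133 against 13.3 ± 6.87 for Gh_D03G117100 and 482 ± 177 against 30.9 ± 14.3 for Gh_A03G080100. MYB39 (Gh_A13G083900), a MYB transcription factor, stood at 431 ± 126 against 20.7 ± 12.5, a log2 ratio of -4.38 ± 0.56, or -4.97 without Xu142fl replicate 1.

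PDF2 was lower at 0 DPA too, with 2234 ± 68.5 against 396 ± 88.5 for Gh_A06G172400. The copy Gh_D10G015500 stood at 988 ± 44.7 against 420.4 ± 91.7, and its log2 ratio of -1.23 ± 0.19 turned to 0.31 under DESeq2 size factors. Without 1 library its edgeR adjusted p was 0.129 (Xu142 replicate 1), 0.140 (Xu142 replicate 2), 0.162 (Xu142fl replicate 2) and 0.190 (Xu142fl replicate 3). With both HDG11 copies this made 4 listed HD-Zip IV genes, 0 higher and 4 lower, too few to pass as a list (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.473). No gene of the H3K27me3 list was listed at -1 or 0 DPA.

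Genes of very-long-chain fatty acid elongation were mostly lower at 0 DPA, 1 higher and 23 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00476; 0.00476 to 0.178 over its alternatives), and DESeq2 factors put 6 of the 24 above a log2 ratio of 0. 3-ketoacyl-CoA synthase 9 (Gh_A01G004600), which adds carbons to fatty acids, stood at 247 ± 72.2 against 11.4 ± 6.52. ECERIFERUM 1 (Gh_A05G335100) fell from 1094 ± 206 to 218 ± 44.2, and ECERIFERUM 3 (Gh_A08G270600), also of wax synthesis, from 490.3 ± 108 to 89.9 ± 15.7. All 7 listed lipid-transfer proteins and all 6 expansin and xyloglucan genes were lower as well, with neither list passing (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.184 and 0.254). The lipid-transfer protein Gh_D10G123300 stood at 4194 ± 2293 against 328 ± 84.7. Actin (Gh_D10G254000) and beta-tubulin (Gh_A07G127700), which build the cytoskeleton, had log2 ratios of -2.42 ± 0.11 and -2.17 ± 0.22. The proteases vacuolar-processing enzyme (Gh_A07G023300) and Pro-X carboxypeptidase (Gh_A05G040900) stood at 588 ± 74.5 against 23.3 ± 9.21 and 462 ± 62.3 against 14.1 ± 12.3, the latter with a log2 ratio of -5.04 ± 0.74, or -6.03 without Xu142fl replicate 1. The nucleoside carrier ENT1 (Gh_D12G161100) stood at 1099.7 ± 11.8 against 57.1 ± 26.2.

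All 12 listed photosynthesis genes were lower at 0 DPA (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0341; 0.0341 to 0.908 over its alternatives). Among genes called by the edgeR refit the list did not pass, without (0.348) or with (0.349) the replicate block (Fisher's exact test, Benjamini-Hochberg adjusted p). The other marker lists were 1 higher and 12 lower for pollen and anther (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.169) and 1 higher and 5 lower for seed storage (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.612). The pollen list held Expansin-A8 and ECERIFERUM 3, and the seed storage list held lipid-transfer proteins, none of which is a marker of those tissues.

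Of the 6 lists that passed at 0 DPA, AP2/ERF, WRKY, calcium and receptor-like kinase genes had mostly higher members. The AP2/ERF list had 16 members higher and 1 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 4.16e-05; 4.16e-05 to 0.0577 over its alternatives). It took in 4 genes named CTR1, a kinase that represses ethylene responses rather than a transcription factor, of which Gh_D05G290300 stood at 137 ± 32.3 against 534 ± 113 and Gh_D06G032600 at 47.1 ± 11.02 against 176 ± 21.8. All 8 listed WRKY factors, known from defense and stress responses, were higher (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00476; 0.00476 to 0.127 over its alternatives). All 6 calcium signalling genes were higher (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0236, and in the edgeR refit 0.0464 without and 0.0520 with the replicate block; 0.0224 to 0.127 over its alternatives), among them CML50 with 177 ± 24.5 against 916 ± 54.0. Receptor-like kinases were 11 higher and 4 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0341, and in the edgeR refit 0.125 without and 0.281 with the replicate block; 0.0341 to 1 over its alternatives), among them the lectin receptor kinase Gh_D02G205400 with 46.7 ± 8.15 against 233 ± 17.0. Among members with a mean of at least 100 normalised reads, 1 receptor-like kinase was higher and 2 were lower, which turned the direction. The auxin (2 higher, 7 lower), gibberellin (2, 4) and ethylene (4, 4) lists did not pass (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.649, 1 and 0.649). The ethylene precursor synthase Gh_A12G256700 stood at 113 ± 22.1 against 844 ± 359, peroxidase 5 at 248 ± 55.5 against 910.2 ± 107 and the factor bHLH35 (Gh_A13G235300) at 34.4 ± 2.72 against 183 ± 40.8.

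Further transcripts were higher at 0 DPA. CDC45 (Gh_A11G148200), part of the DNA replication helicase, rose from 5.45 ± 4.72 to 134 ± 16.1. A casein kinase II subunit (Gh_D11G081200) rose from 9.91 ± 2.48 to 227 ± 7.73, and WD repeat-containing protein 62 (Gh_A09G183000) from 12.02 ± 5.59 to 194 ± 12.2. Root phototropism protein 2 (Gh_A08G231300), which acts in light signalling, stood at 120.3 ± 9.55 against 848 ± 122.8. Methylesterase 10 (Gh_A11G200500) had no read in Xu142 and 122.9 ± 21.9 normalised reads in Xu142fl, at least 125-fold higher. As a list, DNA replication and mitosis genes were 4 higher and 7 lower, which did not pass (Fisher's exact test, Benjamini-Hochberg adjusted p = 1). HMG-Y-related protein A (Gh_A07G085000), a chromatin protein of the histone list, rose from 118 ± 7.02 to 644 ± 64.8.

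The authors' deposited table at 0 DPA listed 1366 of 57326 tested genes, 502 higher and 864 lower, with adjusted p-values up to 0.0131. The edgeR refit called 1144 (398 higher), and 857, 688, 765 and 798 without Xu142 replicate 1, Xu142 replicate 2, Xu142fl replicate 2 and Xu142fl replicate 3; limma with a pseudocount of 0.1 called 522. Factors taken from the listed genes moved the median log2 ratio by 1.10 (TMM) and 1.56 (DESeq2) and gave 501 higher and 303 lower, or 502 higher and 306 lower, so that 62.3% and 62.1% of calls were higher against 36.7% in the table. Of the 77 genes taken by the naming rule, 21 lost the edgeR call when 1 library was left out, of which the text on this day names 1, the PDF2 copy above.

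Some transcripts that marked Xu142fl at the other days were present in Xu142 at 0 DPA. Markers were chosen, after the data were seen, as transcripts with at least 40 normalised reads in Xu142fl at 1 DPA, at most 3% of that in Xu142, and higher in Xu142fl at -1 DPA. On each day those listed with at least 40 normalised reads in Xu142fl on that day were counted. Markers closer to equal in both genotypes would miss the authors' fold criterion, which caps the levels given. At -1 DPA, 137 markers stood in Xu142 at a median of 2.98% of their Xu142fl level (interquartile range, 2.21 to 3.56). At 0 DPA, 110 markers were listed, and 48 of them stood at 10% or more of the Xu142fl level, with medians of 24.1%, 22.7% and 22.2% in Xu142 replicates 1, 2 and 3. A further 55 stood under 5%, with a median of 2.18%, and with medians of 4.13%, 0 and 2.22% in Xu142 replicates 1, 2 and 3. At 1 DPA the median of 139 markers was 0, a low level that their choice had set. CML50 shows this course, with 17.4 ± 4.33, 177 ± 24.5 and 4.91 ± 2.51 in Xu142 at -1, 0 and 1 DPA, each day normalised on its own. The gene groups of 0 DPA were measured in the same Xu142 libraries. Another 28 transcripts were present in Xu142 at 0 DPA, at most 5% as high in Xu142fl, and listed on no other day, against 1 such transcript at -1 DPA and 358 at 1 DPA. Of these, 18 of the 28 and 44 of the 358 were unannotated transcripts by their identifiers, and 20 and 66 had no read in Xu142fl. Without the 28 of 0 DPA, 1338 genes remained listed (502 higher, 836 lower).

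**Figure D1:**
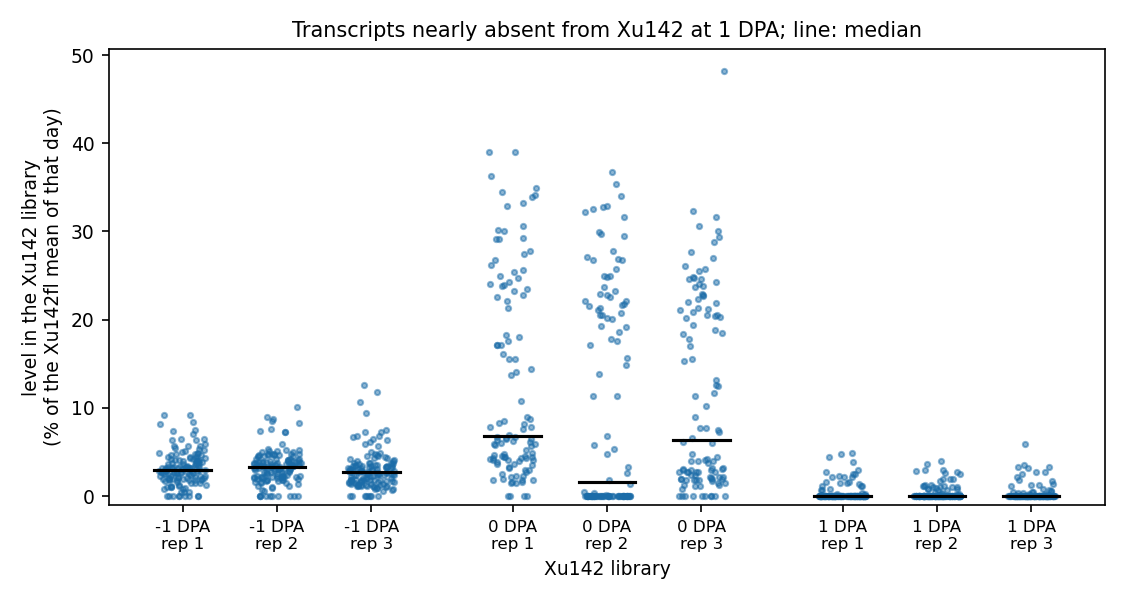
Level of each Xu142fl marker transcript (points) in each Xu142 library (x axis), as % of the Xu142fl mean of that day (y axis), with the median of each library as a line. In the 0 DPA libraries 48 of 110 markers stand at 10% or more, and the low level at 1 DPA was set by the choice of the markers.

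At 1 DPA expansin, pectate lyase and lipid-transfer transcripts named here were far lower in Xu142fl. Expansin-A8 (Gh_D10G123800) stood at 20172 ± 8735 in Xu142 against 3 reads, all in Xu142fl replicate 3, a ratio of 25114 (95% counting interval, 8594 to 121781). Expansin-A4 (Gh_A10G149600, chromosome A10, 83948169 to 83949465) stood at 20376 ± 8858 against 4 reads over the Xu142fl libraries, a ratio of 19026 (95% counting interval, 7431 to 69828). The pectate lyase 5 pair stood at 4881 ± 1185 against 7.13 ± 3.10 and 4187 ± 455 against 13.0 ± 2.42. A pair of lipid-transfer proteins, which carry lipids to the cell surface, fell from 49111 ± 7405 to 115 ± 9.58 (Gh_D10G123300) and from 50967 ± 8714 to 125 ± 24.3 (Gh_A10G150000).

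As lists, expansin and xyloglucan (12 higher, 45 lower), pectin (12, 35), lipid-transfer (4, 19), arabinogalactan (22, 47) and cuticle and wax genes (28, 63) did not pass at 1 DPA (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.124, 0.458, 0.275, 1 and 0.884). Further single transcripts were lower. The wall protein RD22 (Gh_D05G052400) stood at 20481 ± 7522 against 143 ± 44.7, and the vacuolar invertase Gh_A12G223400, which splits sucrose and draws water into the cell, at 11347 ± 5247 against 601 ± 78.1. DET2 (Gh_D04G146600), a steroid reductase of brassinosteroid synthesis, stood at 1852 ± 716 against 137 ± 14.1. Polyphenol oxidase (Gh_A06G204600) stood at 14449 ± 2212 against 6 reads, a ratio of 8995 (95% counting interval, 4132 to 24509.8). Lupeol synthase (Gh_D06G220700), of triterpene synthesis, stood at 3006 ± 331 against 3 reads, a ratio of 3743 (95% counting interval, 1281 to 18149).

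Very-long-chain fatty acid elongation was 6 higher and 62 lower at 1 DPA (Fisher's exact test, Benjamini-Hochberg adjusted p = 3.29e-05; 1.21e-05 to 0.158 over its alternatives). The elongation enzyme 3-oxoacyl-CoA reductase 1 (Gh_A03G153800) fell from 4502 ± 1127 to 27.8 ± 4.77, and ECERIFERUM 1 (Gh_A05G335100) from 5332 ± 845 to 169 ± 17.5. The tubulin and actin list was 27 higher and 120 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000678; 4.85e-05 to 0.432 over its alternatives). All 10 genes named actin and all 7 named tubulin alpha-3 were lower, counts chosen after their values were seen, as are those by protein name below. Actin Gh_A01G249900 stood at 2699 ± 546 against 1 read over the Xu142fl libraries, a ratio of 10081 (95% counting interval, 1809 to 398160.0). The actin copy Gh_D10G254000 stood at 1069.5 ± 149.9 against 38.1 ± 2.57. Calcium signalling genes were 23 higher and 121 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 4.33e-05; 7.85e-07 to 0.0556 over its alternatives), among them the membrane-binding annexin RJ4 (Gh_D10G207700) with 9838 ± 608 against 1519 ± 328.

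HD-Zip IV factors, which govern epidermal cell fate, went both ways at 1 DPA. Both HDG11 copies had no read in Xu142fl, with 707 ± 39.5 (Gh_D12G292500) and 603 ± 43.6 (Gh_A12G298900) in Xu142, at least 881-fold and at least 750.3-fold lower. PDF2 (Gh_A06G172400) had a log2 ratio of -2.05 ± 0.27, and ANTHOCYANINLESS 2 (Gh_D09G047600) of -2.72 ± 0.23. All 4 HDG1 copies were lower, Gh_A09G050500 with 931 ± 404 against 45.6 ± 7.63. All 5 HDG2 copies and all 4 HDG5 copies were higher, with log2 ratios from 1.14 to 1.36, such as 1.36 ± 0.12 for HDG2 Gh_D13G097600 and 1.28 ± 0.19 for HDG5 Gh_A03G003000. The list, 10 higher and 8 lower, did not pass (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0868).

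MYB factors were 71 higher and 79 lower at 1 DPA, a higher share than among other listed genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000624; 0.000241 to 0.365 over its alternatives). All 9 genes named MYB108, a factor of stress and anther development, were higher, and 8 of 9 named MYB306 were lower. MYB306 Gh_D13G184900 stood at 1487 ± 332 against 11.3 ± 2.21. The clock factor LHY sits in this list for its MYB domain. Of the WER genes, Gh_A05G364100 and Gh_D04G061400 were lower, with log2 ratios of -1.52 ± 0.24 and -1.43 ± 0.29. Gh_A11G000100 was higher, with 1.31 ± 0.22, and Gh_A05G412300 stood at 2.86 ± 2.93 against 14.1 ± 2.87, where the edgeR refit missed the threshold (Benjamini-Hochberg adjusted p = 0.0631). Its log2 ratio of 2.30 ± 0.87 was 3.37 without Xu142 replicate 3.

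Genes of the H3K27me3 list were 7 higher and 1 lower at 1 DPA (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00584; 0.000225 to 0.518 over its alternatives). All 3 listed copies of REF6, a demethylase that removes this mark, rose. Gh_D07G059400 (chromosome D07, 6453558 to 6463070) stood at 437 ± 19.6 against 993 ± 159, Gh_A07G058900 (chromosome A07, 7056529 to 7066236) at 456 ± 23.9 against 963 ± 166 and Gh_D09G261000 (chromosome D09, 52258025 to 52266337) at 632 ± 31.2 against 1311 ± 238. Their log2 ratios were 1.18 ± 0.14, 1.08 ± 0.15 and 1.05 ± 0.16. The other 5 members were copies of JMJ25, known as a demethylase of H3K9 and not of H3K27, with 4 higher and 1 lower. JMJ25 Gh_A12G274500 stood at 1295 ± 135 against 3084 ± 806, and the lower copy Gh_A11G104700 at 64.1 ± 25.6 against 14.8 ± 7.31. With 1 gene per protein name and direction, 3 entries were left and the call ended (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.518).

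Ribosomal protein genes were 17 higher and 496 lower at 1 DPA (Fisher's exact test, Benjamini-Hochberg adjusted p = 1.49e-62; 1.49e-62 to 2.63e-15 over its alternatives). L24-1 (Gh_A09G197400) fell from 1721 ± 283 to 26.5 ± 9.48. Heat-shock genes were 21 higher and 84 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0146; 0.0146 to 0.158 over its alternatives), among them heat shock cognate 70 (Gh_D09G167900) with 1102 ± 240.2 against 101 ± 28.3. DNA replication and mitosis genes were 76 higher and 30 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 3.16e-15; 9.63e-21 to 2.90e-05 over its alternatives). Its terms also matched 43 reverse transcriptases and other transposon genes (34 higher), which copy RNA into DNA, beside 48 kinesins (29 higher), the microtubule motors, and 15 other members (13 higher) such as DNA polymerases and MCM5. With the terms matched to the full protein name alone, 33 members were higher and 19 lower, at the upper bound of that range. CDC45 (Gh_A11G148200), outside that list by its name, stood at 138 ± 9.94 in Xu142fl against 1 read in Xu142, a ratio of 352 (95% counting interval, 63.2 to 13901). The histone list was 21 higher and 3 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 3.82e-07; 6.05e-08 to 0.0403 over its alternatives). It held 7 genes named IDM1, a histone acetyltransferase, and 4 named ASHH2, a histone methyltransferase, and with the search terms matched to the full protein name alone 7 were higher and 3 lower. Histone H2B.3 (Gh_A13G255900), a core histone, rose from 602 ± 148 to 2551 ± 609.

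Some lists of hormone genes and transcription factors had a higher share of higher members at 1 DPA than the other listed genes, but the brassinosteroid (9 higher, 8 lower), jasmonate (15, 18), MADS-box (4, 6), SPL (4, 5) and TCP (1, 10) lists did not pass (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.194, 0.215, 0.812, 0.602 and 0.194). AP2/ERF genes were 52 higher and 31 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.90e-07; 2.90e-07 to 0.158 over its alternatives), with 7 of 7 named ERF1A and 4 of 4 named RAV1 higher. The 5 genes named peptide chain release factor 1-3, which end translation, also matched the terms and were all lower. RAV1 (Gh_D12G187900), a repressor of growth, rose from 70.0 ± 31.4 to 799 ± 71.6. Ethylene synthesis and sensing was 19 higher and 10 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00154; 1.69e-05 to 0.2497 over its alternatives), with all 9 genes named EBF2, which degrades an ethylene factor, and all 4 ETR2 receptors higher. Gibberellin genes were 23 higher and 16 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00259; 0.000343 to 0.0140 over its alternatives). The synthesis genes GA20ox2 (4 of 4) and GA3ox1 (3 of 3) and the receptor GID1B (3 of 3) were higher, whereas the small secreted proteins GASA4 and Snakin-1 were lower (3 of 3 each).

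The cytokinin (18 higher, 13 lower), auxin (42, 41) and abscisic acid (14, 10) lists passed as well (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00893, 0.00197 and 0.0303). Over their alternatives the adjusted p ran from 0.00893 to 0.171 for cytokinin, from 0.000327 to 0.0796 for auxin and from 0.0303 to 0.603 for abscisic acid (Fisher's exact test, Benjamini-Hochberg). The cytokinin phosphotransfer protein AHP1 (Gh_D11G293800) stood at 589.6 ± 97.3 against 1576 ± 167. NAC (28, 23), WRKY (20, 16) and bHLH (40, 25) factors also passed (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00386, 0.0146 and 1.02e-05), with ranges over their alternatives of 0.000677 to 0.849, 0.00910 to 1 and 1.02e-05 to 0.0157. The NAC2 pair, stress-related NAC factors, stood at 91.3 ± 10.7 against 360.0 ± 15.5 (Gh_A06G051200) and 56.6 ± 7.77 against 261 ± 8.29 (Gh_D06G050200). MYC2 (Gh_A03G005600), the central factor of jasmonate responses, stood at 114 ± 17.1 against 424 ± 13.8. Receptor-like kinases (104, 103) and disease-resistance proteins (81, 71) had the same adjusted p (Fisher's exact test with Benjamini-Hochberg adjustment, 7.93e-07; 1.78e-08 to 0.0104 and 7.85e-07 to 0.0925 over their alternatives). Cellulose synthesis genes (26, 29) passed narrowly (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0434; 0.00910 to 0.335 over its alternatives), and their median log2 ratio of -1.09 turned to 0.13 under TMM and 0.18 under DESeq2 factors. The marker lists did not pass, with photosynthesis 16 higher and 47 lower, pollen and anther 19 and 54, and seed storage 10 and 28 (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.402, 0.387 and 0.602). By protein name 14 of the 73 pollen members and 9 of the 38 seed storage members matched. Both lists therefore say little about pollen, embryo or endosperm.

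**Figure D2:**
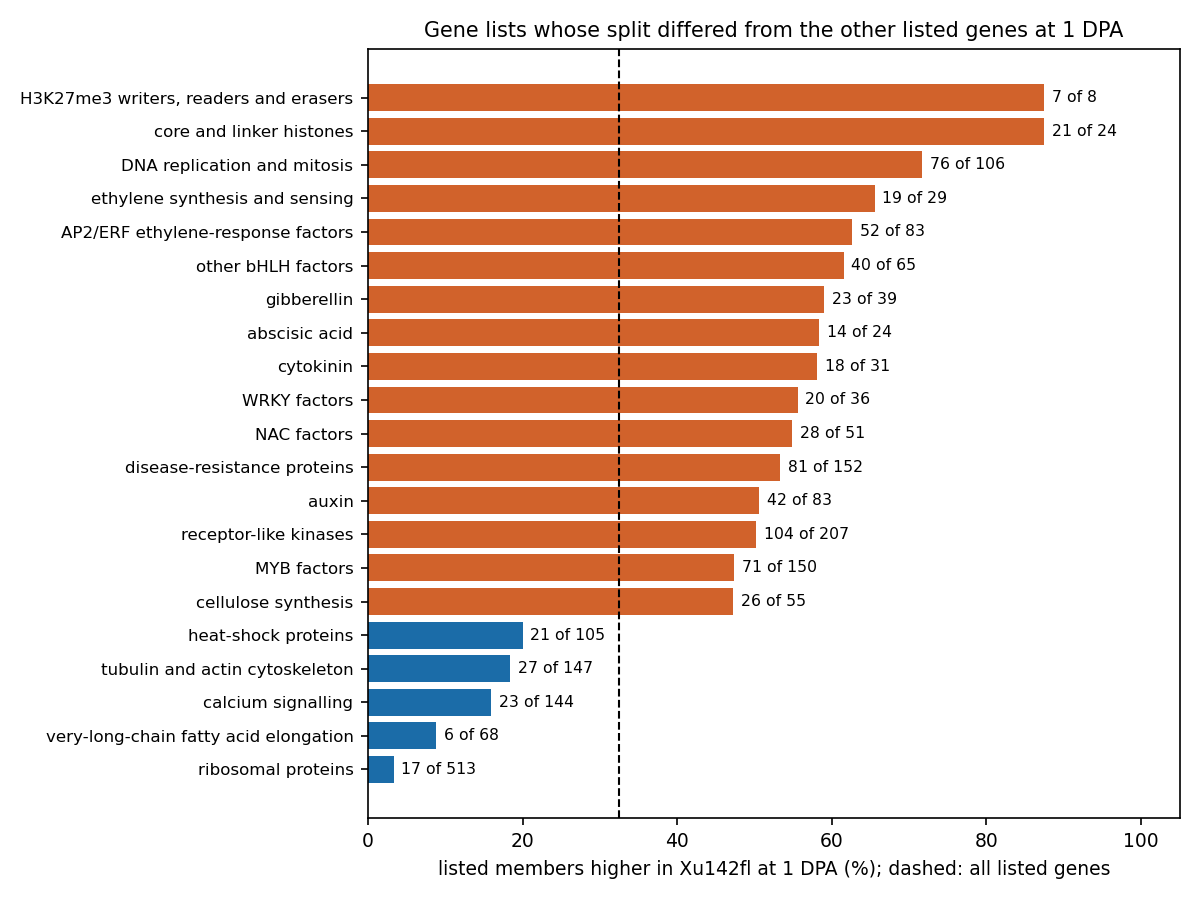
Share of listed members higher in Xu142fl at 1 DPA (x axis, %) for the 21 gene lists whose split differed from the other listed genes, with higher and listed members printed beside each bar; the dashed line marks 32.5%, the share over all listed genes. Ribosomal protein genes lie lowest (17 of 513) and the H3K27me3 list highest beside the histone list (7 of 8; 21 of 24), and the median of the cellulose list turned from lower to higher under TMM and DESeq2 factors.

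The authors' deposited table at 1 DPA listed 10793 of 61474 tested genes, 3505 higher and 7288 lower, with adjusted p-values up to 0.0497. The edgeR refit called 10130. Factors from the listed genes moved the median log2 ratio by 1.20 (TMM) and 1.24 (DESeq2) and gave 3505 higher and 2411 lower, or 3505 higher and 2486 lower, so that 59.2% and 58.5% of calls were higher against 32.5% in the table. Members above a log2 ratio of 0 then numbered, under TMM and DESeq2 factors, 134 and 164 of 513 ribosomal protein genes, 43 and 46 of 147 tubulin and actin genes, 46 and 51 of 144 calcium genes, 35 and 38 of the heat-shock genes, and 32 and 34 of 51 NAC genes. The median log2 ratio of ribosomal protein genes moved from -1.37 to -0.18 and -0.14. With 1 gene kept per protein name and direction, 14 of the 21 list calls of this day ended.

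**Figure D3:**
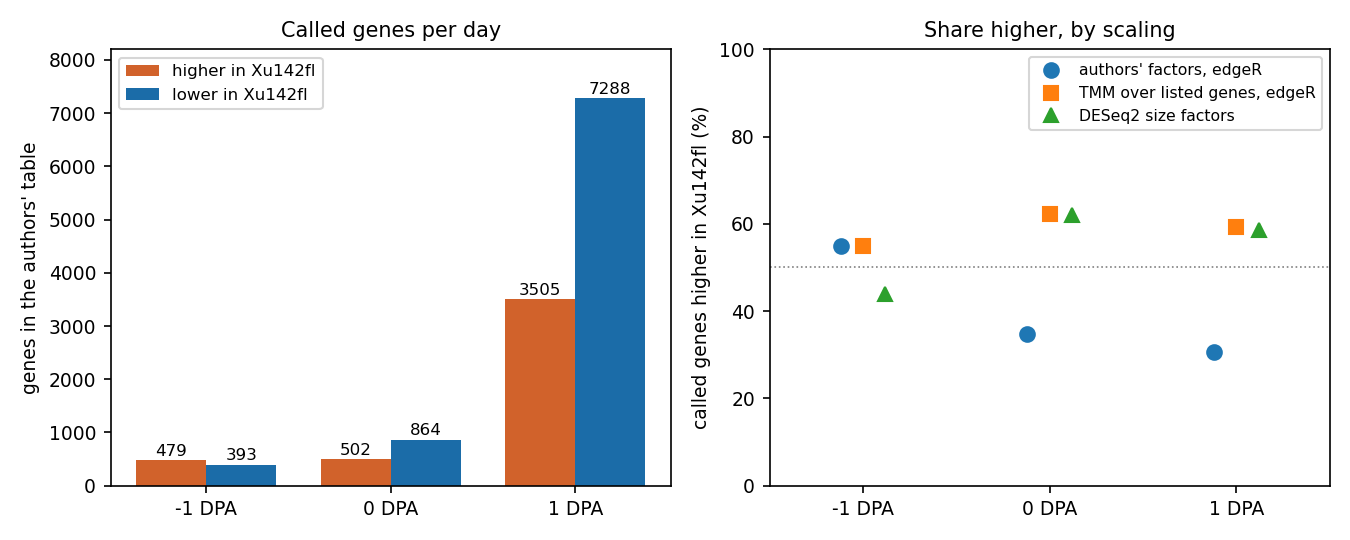
Left, genes in the authors' deposited tables per day (y axis, genes; bars, higher or lower in Xu142fl), rising from 872 at -1 DPA to 10793 at 1 DPA. Right, share of refit calls higher in Xu142fl (y axis, %) under the authors' factors, TMM factors and DESeq2 size factors (symbols), with a dotted line at 50%. At 1 DPA the share turns from 30.7% to 59.2% and 58.5% under factors that center the listed genes on themselves.

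Across days, 526 genes were listed at all 3, and 522 of them kept 1 direction, 293 higher and 229 lower. The lower ones included PDF2 (Gh_A06G172400) and the aquaporin PIP-type 7a (Gh_D06G194600), the latter with log2 ratios of -3.26 ± 0.38, -2.68 ± 0.17 and -3.73 ± 0.21 at -1, 0 and 1 DPA. Ribosomal protein L11-2 (Gh_D10G037000) had -2.42 ± 0.17, -3.14 ± 0.32 and -4.01 ± 0.14. The higher ones included CML50 with 5.68 ± 0.22, 2.37 ± 0.13 and 7.40 ± 0.43, and TxlA (Gh_D06G014800) with 5.07 ± 0.33, 2.18 ± 0.21 and, from 5 reads in Xu142 at 1 DPA, 6.60 (95% counting interval, 5.38 to 8.23). Genes listed at both -1 and 0 DPA numbered 559, of which 99.8% had the same direction (Fisher's exact test, p = 3.44e-164). The pair -1 and 1 DPA shared 700 genes, 96.0% in the same direction (Fisher's exact test, p = 2.80e-155), and the pair 0 and 1 DPA shared 1145, 97.6% in the same direction (Fisher's exact test, p = 1.17e-271). In all, 11153 genes were listed on at least 1 day, 139 at -1 DPA alone, 188 at 0 DPA alone and 9474 at 1 DPA alone; an absence from a table does not show that a gene was equal there.

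**Figure D4:**
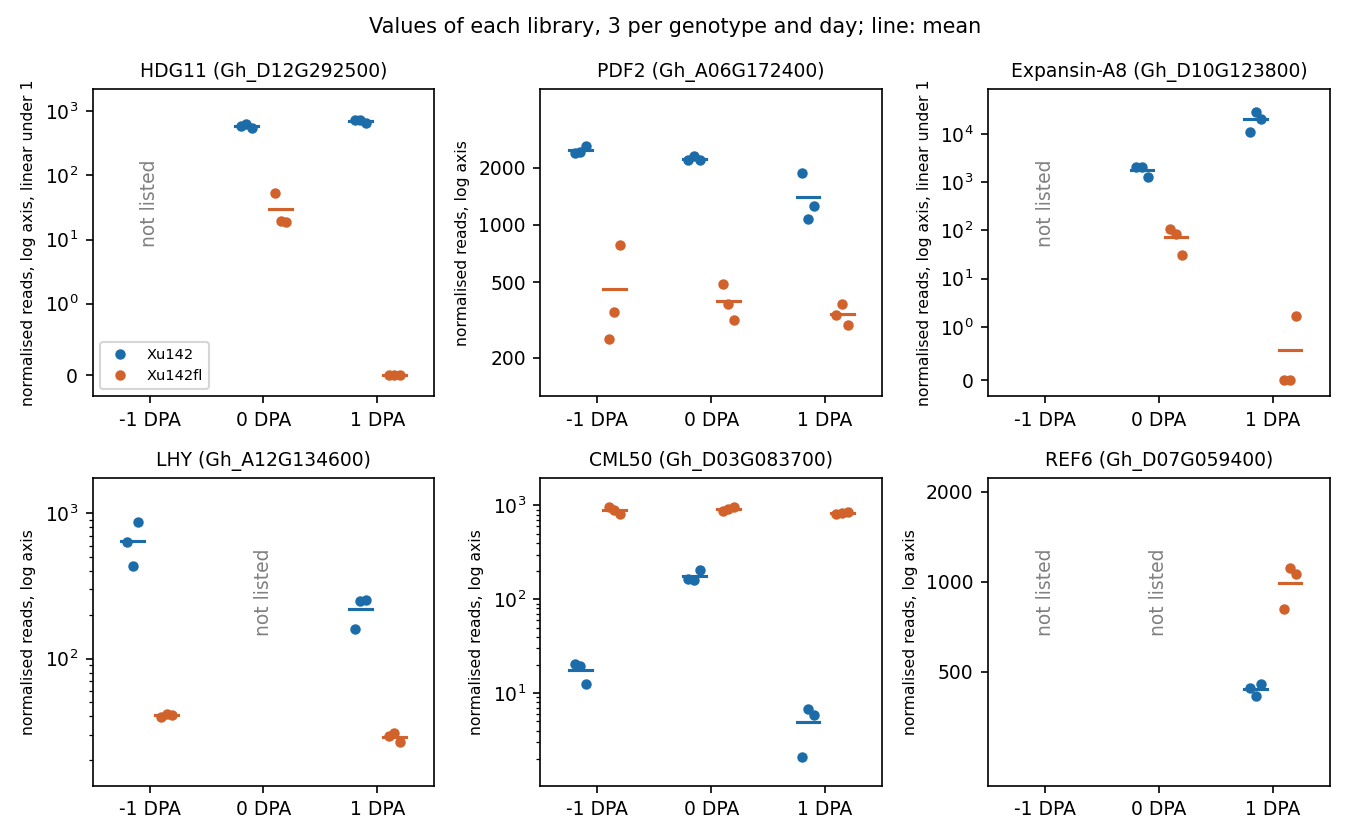
Normalised reads of 6 genes (y axis, log scale, linear under 1 for HDG11 and Expansin-A8) in each library of Xu142 and Xu142fl (points) at -1, 0 and 1 DPA (x axis), with the mean as a line; days on which a gene was absent from the authors' table are marked as not listed. PDF2 stays near 2466 to 1407 in Xu142 and 460.4 to 339.6 in Xu142fl, CML50 is higher in Xu142fl on every day, and REF6 is listed at 1 DPA only (436.9 against 993).

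Both subgenomes were represented about equally. At 1 DPA, 5209 listed genes lay in the A and 5349 in the D subgenome, at -1 DPA 431 and 420, and at 0 DPA 636 and 703. The split of higher and lower genes passed the test on 1 chromosome and day, D04 at 0 DPA, with 3 genes higher and 32 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00648). D02 at -1 DPA (33 higher, 12 lower) and D07 at 1 DPA (104, 293) did not pass (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.342 and 0.163). Genes on unplaced contigs, not tested, were 147 higher and 88 lower at 1 DPA. Transcripts that the authors' annotation leaves without a gene model name made up 262 listed genes at -1 DPA (188 higher), 359 at 0 DPA (153 higher) and 1194 at 1 DPA (572 higher).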

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

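The interaction fits given here were chosen only after the directions at each day had been seen. They asked, among genes listed on both days of a pair, whether the genotype difference itself differed between days (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over those genes). It differed for 85 genes between -1 and 0 DPA, for 263 between -1 and 1 DPA and for 521 between 0 and 1 DPA. Of these, 1, 28 and 28 genes were listed in opposite directions on the days of the pair, which is every gene so listed. Genes already called in opposite directions on the same reads could hardly fail this test. Their interaction p-values are therefore no separate support. The 2 counts with 0 DPA rest on its Xu142 libraries, in which 48 of 110 Xu142fl markers stood at 10% or more of the Xu142fl level. Of these 48 markers, 47 are among the 85 genes and all 48 among the 521. The count between -1 and 1 DPA is touched too, since 92 of its 263 genes are Xu142fl markers. Their low level in Xu142 at 1 DPA was set by their choice. At -1 DPA the 137 markers stood in Xu142 at a median of 2.98% of their Xu142fl level, which a small share of Xu142fl RNA or reads would give.

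The WER gene Gh_D04G061400 drew attention because it was higher in Xu142fl at -1 DPA (30.5 ± 2.996 against 103 ± 16.1) and lower at 1 DPA (177 ± 27.5 against 66.0 ± 20.5), each day normalised on its own. The difference of its log2 ratios, 1 DPA minus -1 DPA, was -3.19 (edgeR interaction, Benjamini-Hochberg adjusted p = 2.48e-07). The genes named next were chosen after their values were seen, except xyloglucan endotransglucosylase/hydrolase 2. Both copies of ATHB-40, a homeodomain-leucine zipper factor, were lower at -1 DPA and higher at 1 DPA, with log2 ratios of -1.61 ± 0.12 and 2.19 ± 0.46 for Gh_A11G196800 (edgeR interaction, Benjamini-Hochberg adjusted p = 5.73e-07). Gibberellin 3-beta-dioxygenase 1 (Gh_D06G223900), which makes active gibberellin, moved the same way, with -1.61 ± 0.22 and 1.41 ± 0.28 (edgeR interaction, Benjamini-Hochberg adjusted p = 5.40e-07). Xyloglucan endotransglucosylase/hydrolase 2 (Gh_D02G024500) went from 3.01 ± 0.28 to -3.13 ± 0.37 (edgeR interaction, Benjamini-Hochberg adjusted p = 2.27e-09), and the transporter NRT1/PTR FAMILY 6.1 (Gh_D02G195800) from 1.46 ± 0.17 to -5.45 ± 0.36 (edgeR interaction, Benjamini-Hochberg adjusted p = 7.12e-11). The 1 gene with opposite directions at -1 and 0 DPA was a guanine nucleotide-binding protein beta subunit-like gene (Gh_A06G013400), with -2.19 ± 0.30 and 1.93 ± 0.26.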

How the results depend on the processing

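The tests with full protein names, TMM factors, block calls for lists, annotated genes only, without one-day transcripts and with interactions were chosen only after the data were seen; the other alternatives were planned. Over the results that answer a comparison, 518 values under an alternative were tallied as unchanged. Another 36 fell short of the threshold, 4 newly passed it, 9 counts moved by more than 1.5 times and 1 list turned direction. For lists that passed, unchanged meant the same direction and a pass. For the other lists it meant no pass, in whichever direction. For counts it meant a move of at most 1.5 times, whatever the split into higher and lower. Turned directions were therefore sought only in lists with a pass. For single named genes 1657 values kept their direction and passed, and 82 fell short of the threshold. The 518 include a planned setting, a deposited log2 fold of at least 1. Every listed gene met it beforehand, so that its values repeat the main result. These tallies leave out the sign under other factors: with DESeq2 factors 2 named genes of -1 DPA and 5 of 0 DPA changed sign, and the larger side of the calls turned on every day (43.9%, 62.1% and 58.5% higher), as with TMM at 0 and 1 DPA (62.3% and 59.2%). Because those factors center the list of called genes on itself, these turns do not test the direction of the calls. Where a call ended for another reason than fewer genes or libraries, the cause was not tested.

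Against the authors' calls, counts of called genes moved by more than 1.5 times only at 0 and 1 DPA, and part of this is the change of tool. At 0 DPA, against 1366 deposited calls and 1144 of edgeR with the authors' factors, TMM gave 804, DESeq2 808, and limma with a pseudocount of 0.1 gave 522. Leaving out 1 library in edgeR gave 688 (Xu142 replicate 2) to 1016 (Xu142 replicate 3), with 857, 765 and 798 without Xu142 replicate 1, Xu142fl replicate 2 and Xu142fl replicate 3. Of the edgeR counts of 0 DPA, 688 alone differed from 1144 by more than 1.5 times. At 1 DPA, against 10793 deposited and 10130 edgeR calls, TMM gave 5916 and DESeq2 5991. At -1 DPA the range was 701 (DESeq2) to 872, and leaving out 1 library gave 858 to 872. Annotated genes alone numbered 610, 1007 and 9599.

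List results are adjusted p-values of Fisher's exact test with Benjamini-Hochberg adjustment. With 1 gene per protein name and direction, which leaves fewer genes, calls ended at -1 DPA for heat shock (0.158) and at 0 DPA for WRKY (0.101), fatty acid elongation (0.178), calcium (0.0570), receptor-like kinases (0.219) and photosynthesis (0.162). At 1 DPA they ended for MYB (0.365), WRKY (0.395), NAC (0.849), AP2/ERF, fatty acid elongation and heat shock (0.158 each), H3K27me3 and abscisic acid (0.518 each), cellulose (0.335), cytoskeleton (0.432), auxin (0.0796), ethylene (0.2497), cytokinin (0.171) and disease resistance (0.0925). With members of a mean of at least 100 alone, calls ended at 0 DPA for WRKY and calcium (0.127 each), AP2/ERF and fatty acid elongation (0.0577 each) and photosynthesis (0.908), and receptor-like kinases turned direction (1 higher, 2 lower; adjusted p = 1). At 1 DPA that filter ended the calls of WRKY (1), cellulose (0.0967), abscisic acid (0.158), calcium (0.0556) and heat shock (0.119), and HD-Zip IV (0.0140), cuticle and wax (0.0181) and jasmonate (0.0368) then passed. With full protein names photosynthesis passed at -1 DPA (0.0131) and not at 0 DPA (0.190), and cytokinin (0.0832) and abscisic acid (0.603) did not pass at 1 DPA.

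On the edgeR calls of 0 DPA, receptor-like kinases (0.125) and photosynthesis (0.348) did not pass even without the replicate block, and with it stood at 0.281 and 0.349. The block itself ended the calcium call (0.0464 without, 0.0520 with it) and changed no other list call; edgeR called 983 genes with it against 1144. At -1 and 1 DPA the replicate numbers gave deviations of same-numbered libraries correlated at 0.006, 0.040 and 0.025, and at 0.070, 0.042 and -0.024. The numbers were therefore not taken to pair the libraries on these days. There the block gave 872 genes against 872 and 10249 against 10130. At 0 DPA every library correlated best with that of its own number, and at 1 DPA not every library did.

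In simulated data, edgeR called 62% of 2-fold and 98% of 4-fold changes at -1 DPA, 1% and 54% at 0 DPA, and 32% and 89% at 1 DPA, among 100 genes changed by each fold. With so few changed genes the cut was stricter than in the refits, whose sensitivity these rates do not give.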

Other observations

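Except for the thinning of reads, the tests given here were chosen only after the results were seen. Listed genes of the circadian clock were all lower in Xu142fl at -1 DPA, 0 higher and 16 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 4.88e-06 over the 2 lists chosen after the data were seen). Because the list was chosen after these values were seen, its p-value is no separate support. The 16 genes include LHY, REVEILLE factors and APRR5, which drive the daily rhythm of transcription. A further LHY copy, Gh_A12G134700, stood at 1017 ± 206 against 333 ± 24.0, and APRR5 (Gh_A11G108700) at 60.0 ± 13.0 against 18.8 ± 2.08. No clock gene was listed at 0 DPA, and 6 were higher and 6 lower at 1 DPA (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.222). The fall of LHY Gh_D12G134800 was larger at -1 DPA than at 1 DPA (difference of the log2 ratios 1.57, edgeR interaction, Benjamini-Hochberg adjusted p = 0.00111), as was that of Gh_A12G134600 (1.04, adjusted p = 0.0307), whereas the test did not pass for APRR5 (-0.12, adjusted p = 0.846). The labels used here give no hour of sampling.

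Transcripts of E6, a protein known from cotton fibers, parted between the genotypes day by day. E6 Gh_A05G145000 stood at 404 ± 36.4 against 169.6 ± 42.2 at -1 DPA, 2885 ± 1327 against 279 ± 97.2 at 0 DPA and 54587 ± 18476 against 157 ± 44.2 at 1 DPA, each day normalised on its own. Its log2 ratio differed between -1 and 1 DPA by -7.20 (edgeR interaction, Benjamini-Hochberg adjusted p = 1.18e-10). A gene without a protein name, Gh_A02G045600 (chromosome A02, 4929467 to 4930366), followed the same course, with 425 ± 62.3 against 131 ± 11.9, 2253 ± 1385 against 74.8 ± 9.40 and 84905 ± 13648 against 30.8 ± 4.24. Transposon-related genes had more higher members than other listed genes, 31 higher and 11 lower at -1 DPA, 28 and 28 at 0 DPA and 128 and 71 at 1 DPA (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0162, 0.0466 and 4.89e-20). All these genes were chosen after their values were seen, so that their p-values are no separate support.

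At 0 DPA, 48 of 110 listed Xu142fl markers stood at a median of 23.2% of their Xu142fl level in Xu142, and 55 at 2.18%. Markers that missed the authors' fold criterion on that day are not counted, which caps these levels in the Xu142 libraries. Xu142fl RNA or reads mixed into these libraries would put every marker at 1 share per library, but 47.9% of values lay outside the Poisson range of 1 share and 33.3% below it, which argues against it as the whole cause. RNA of another genotype in the Xu142 libraries of that day would also bring transcripts that Xu142fl lacks, and 28 such transcripts were listed on no other day, against 1 at -1 DPA but 358 at 1 DPA, and 18 of the 28 were unannotated transcripts and 20 had no read in Xu142fl, against 44 and 66 of the 358, a difference in kind that was not tested. Chromosome blocks of another genotype would set neighbouring markers at the same level, and 49 of 77 neighbouring pairs were alike against 38.3 by chance (permutation p = 0.00945). Neighbours could also be alike if Xu142 itself expressed them together, so that the test cannot tell these sources apart. RNA of another genotype may be a source, and expression of these transcripts in Xu142 on that day alone, which was not tested, stays open beside it.

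At -1 DPA, 137 markers stood in Xu142 at a median of 2.98% of their Xu142fl level. With 1 share per library, 1.70% of values lay outside the Poisson range and 0 below it. A small share of Xu142fl RNA or reads in the Xu142 libraries of -1 DPA would give this. At 1 DPA, where the choice of markers had set the low level, 2.40% of values lay outside and 0 below. Passing at such low levels therefore says little. An exchange in both directions stays open. Of the values of 39 Xu142 markers in the Xu142fl libraries, 39.3% lay outside the range of 1 share and 25.6% below it. Their medians were 3.78%, 7.39% and 17.2% in replicates 1, 2 and 3, but expression in Xu142fl itself would add to a share and raise the fitted one. Of the 117 values 0 lay below the share found in the Xu142 library of the same number, and only 21 could have done so. Low expression of the markers in Xu142 at -1 DPA alone was not tested and stays open.

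Many more genes were listed at 1 DPA (10793) than at -1 DPA (872) or 0 DPA (1366). Deeper sequencing is argued against as the whole cause, as far as the 526 genes listed at all days measure depth: by their median reads (53.9, 52.0 and 44.75 per library at -1, 0 and 1 DPA) 1 DPA was not deeper, and with its reads thinned to 48.5% or 47.4%, the ratio of total reads at -1 or 0 DPA, edgeR still called 9218 and 9174 genes. The higher total of 1 DPA lay mostly in the Xu142 libraries (267167 to 288034 reads, against 77997 to 137342 in Xu142fl), and depth over all genes is unknown. The fold criterion, which was stricter at -1 and 0 DPA, is argued against as well, since at a common adjusted p of 4.93e-05, recovered by rank for listed and unlisted genes alike, 2055, 985 and 10299 genes passed at -1, 0 and 1 DPA, a ratio of 5.01 to the next highest day. Whether the ovules differed in their share of fiber cells or in regulation within each cell was not tested and stays open.

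For other splits of the 6 libraries of a day, 1 of 10 splits, the real one, gave as many edgeR calls on each day, and 10 splits are too few for a share under 0.05. The real splits gave 872, 1144 and 10130 calls and the highest other split 0 on each day, with at most 0, 7 and 157 genes at an unadjusted p under 0.05 in edgeR; no other tool was run on the splits. The listed genes were chosen on the real split, which favours it. At 0 DPA, where the replicate numbers were taken to pair the libraries from the values alone, 4 of the 10 splits part all pairs. The other 3 of those 4 gave 0 calls.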
